A study of Arabidopsis thaliana with 6 samples.

How the data were processed

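Transcript levels were measured on Affymetrix Arabidopsis arrays with biotin-labelled RNA from leaves of Arabidopsis thaliana. The plants were 3 weeks old, and the 6 arrays comprise 3 of wild type Columbia plants and 3 of the activation-tagged line tac1-1D. The design text describes the 3 arrays of each genotype as biological replicates. The submitters' processing notes name the tools MAS5 and GCOS version 1.3, without saying which step each performed.

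The deposited table holds log2 values of array signals, 1 column per array, for 22810 probe sets. When the deposited log2 values are turned back into signals, the lowest is 0.1 on every array. The mean signal with 2% of the values trimmed from each end is 500 on every array, so the arrays had been scaled to a common mean before deposit. No background reading or detection call was used here. A low signal can therefore not be separated from background, and the fold change of a probe set that is low in one group is uncertain.

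The 64 array control probe sets were set apart, and the other 22746 were tested. The probe annotation supplied with the series names 1 gene for 13513 probe sets and several genes for 503. It names none for 8730 probe sets (38.4%), which are unnamed here and not without a gene. Of the probe sets with 1 gene, 13436 matched a locus of the TAIR10.1 annotation, and together they stand for 13286 genes. Coverage is uneven. Only 14.6% of annotated protein-coding genes with a name have a named probe set, against 63.1% of those known only by a locus code. BT2, fixed beforehand as a named gene, has no named probe set and was not analysed here. The files name no genome build, so the TAIR10.1 annotation was used only for names and for gene order, and no coordinates are given.

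Differences were fitted with limma version 3.58.1 in R 4.3.3. A linear model with genotype as its one term was fitted to the log2 values, and variances were moderated with an intensity trend. The test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets. Every adjusted p for a probe set is from this limma fit unless another test is named, and the threshold was 0.05. All differences are tac1-1D minus wild type on the log2 scale, with the standard error (SE) of the fit, and signals are given as mean ± SD over 3 arrays. The plan had assumed linear signals and a pseudocount of 16, with no pseudocount if the values were already logs. None was added, and 16 became an alternative. Differences on the log2(signal + 64) scale are given for many, but not all, genes with low signals. These p-values measure a difference against the spread among these 6 arrays, and their number limits the precision.

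The design, TAC1 and BT2, and the rules for choosing the other named genes were fixed before the data were examined. Those other genes were chosen by the values tested here. The named genes are TAC1 and BT2, the 14 largest rises and the 14 largest falls past the threshold without overlap between groups, and genes past the threshold among list members and neighbours of TAC1. For a fixed list past its test with no such member, up to 2 members are given as values. Where several probe sets stood for a gene, the one with the highest mean was used. A set of 25 gene lists with 446 members had been fixed from general knowledge. Only 50 members were measured by a probe set with 1 gene, and 4 were left out because symbol and locus did not match. 6 lists had no measured member: the BT family, DNA damage response, nitrate response, ethylene response, flower markers and seed storage markers. Another 13 had 1 or 2. The remaining 6 lists, with at least 3 members, were tested with limma's camera at its preset correlation of 0.01, adjusted over the 6. The minimum of 3 was set after the number of measured members was known. Counts of members past the threshold are given over all probe sets and adjusted over the list alone. Root hair, other root and ER body lists, symbol families and genes grouped by chromosome were added after values had been seen.

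The procedure was tested on simulated data. In a simulated comparison of tac1-1D with wild type over 22746 probe sets, 100 probe sets were changed by 1 on the log2 scale and 100 by 2. The fit recovered 19% of the former and 68% of the latter, with 6 false calls among 93. The simulated noise was normal, with the variances that the fit itself had estimated. These figures therefore do not check the moderated variances or the intensity trend. For the gene lists, 100 simulations without any change over 13286 genes gave at least 1 list past the threshold in 21, where at most 5 would be proper. At an unadjusted p under 0.05 the flavonoid list was called in 24 of them, the abscisic acid list in 14, cell wall loosening in 6, auxin response in 4, guard cell markers in 2 and photosynthesis in 1. The test with the preset correlation was therefore too liberal for the flavonoid and abscisic acid lists. The simulated probe sets varied independently, so the counts of the other lists do not clear them for genes that vary together. With an estimated correlation these counts were 12 and 5 for the flavonoid and abscisic acid lists, and at most 2 for the others. The flavonoid list thus stayed above its proper rate. The p with an estimated correlation is given beside each list.

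The alternatives were other pseudocounts, a filter at the 40th percentile of mean signal, quantile normalization, median centring, other variance models, a replicate block, leaving out each array, a plain t-test, other thresholds, other list tests and other numbers of neighbouring genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.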

Results

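Leaf transcript levels were compared between 3 wild type Arabidopsis arrays and 3 arrays labelled tac1-1D. The tac1-1D line carries an activation tag, a T-DNA with enhancers that can raise transcription of nearby genes. It is described as overexpressing TELOMERASE ACTIVATOR 1 (TAC1), which encodes a zinc-finger transcription factor. The comparison asks which other transcripts differ in leaves of this line. Median signals were 178.6 to 181.7 on the wild type arrays and 185.7 to 195.1 on the arrays labelled tac1-1D, and 14.24% to 17.48% of the tested probe sets had signals under 20. Pearson correlations of log2 values, taken across probe sets, were 0.941 to 0.950 within wild type and 0.948 to 0.957 within tac1-1D. Between the genotypes they were 0.925 to 0.937. The first principal component held 34.4% of the variance and had the wild type arrays on one side and the tac1-1D arrays on the other.

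TAC1 itself was not higher in the arrays labelled tac1-1D. Its probe set (AT3G09290) read 9.03 ± 0.643 (SD, n = 3) in wild type and 4.5 ± 1.15 (n = 3) in the arrays labelled tac1-1D. The log2 difference was -1.03 with an SE of 0.589 and an adjusted p of 0.47 in the limma fit. Its signal was at most 9.5 on any array. The transcript that should mark the line therefore does not check the labels, and every direction below refers to arrays as labelled.

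Among the genes around TAC1, PYK10 stood apart. PYK10, a β-glucosidase abundant in roots and in the ER bodies of seedlings, lies 3 genes away from TAC1. It had a signal of 73.6 ± 19.2 (SD, n = 3) in wild type and 7367 ± 329 (n = 3) in the arrays labelled tac1-1D. The log2 difference was 6.68 with an SE of 0.192 and an adjusted p of 1.38e-06 in the limma fit, and on the log2(signal + 64) scale it was 5.76. Of the 20 annotated genes within 10 places of TAC1, 9 had a named probe set, and PYK10 was the 1 that passed the threshold over all probe sets and also adjusted over the list alone. The median log2 difference of the others was -0.144. Between TAC1 and PYK10, the named gene AT3G09280 differed by -0.36 (SE 0.4, adjusted p = 0.752). As a set the 9 neighbours were not shifted (camera p = 0.342; p = 0.384 with an estimated correlation).

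**Figure D1:**
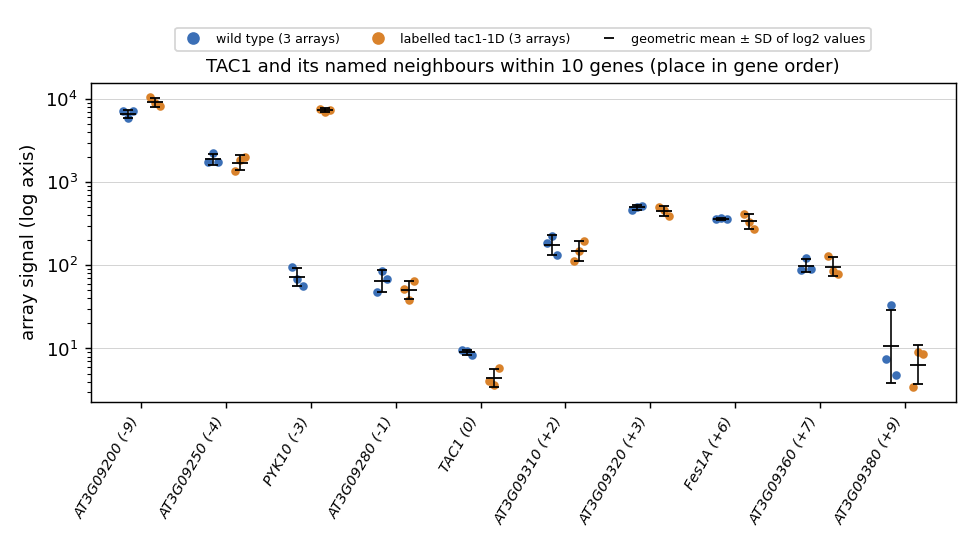
Array signal (log axis) of TAC1 and of the 9 named genes within 10 places of it in gene order, with 3 arrays per genotype as points and the geometric mean ± SD of the log2 values as bars. The 3 arrays labelled tac1-1D lie far above wild type for PYK10, and TAC1 reads at most 9.5 on any array.

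Among the probe sets past the threshold, far more rose than fell in the arrays labelled tac1-1D. The median log2 difference over all probe sets was -0.012. 561 of 22746 probe sets passed the threshold, 476 of them higher and 85 lower, so that 84.8% of the calls were rises. The rises had a median log2 difference of 2.08 and the falls of -1.06. At least 2-fold differences were found for 428 rises and 47 falls, and 16-fold ones for 80 rises and 1 fall, the latter of a probe set without a named gene. The groups did not overlap in any of the 561, as in 20.6% of all probe sets, where chance gives 10%. Of the rises 212 belong to probe sets with 1 named gene and 244 are unnamed, and of the falls 42 and 42. The wild type mean signal was under 50 for 170 of the rises, and for those the fold is uncertain. The count of calls rested on few arrays: it was 212 without tac1-1D replicate 2, 217 without tac1-1D replicate 3 and 337 without wild type replicate 2. The falls alone numbered 11, 13 and 18 without these arrays in turn, 48 without wild type replicate 1 and 145 without tac1-1D replicate 1, and 140 with median centring. The count of all calls was 265 without the intensity trend and 96 when each probe set was tested on its own variance.

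The 14 largest rises among named genes, PYK10 and the auxin-conjugating enzyme gene GH3.3 among them, were all over 5 on the log2 scale of the file, an order that holds without a pseudocount. AT5G44380, a berberine-bridge type oxidoreductase, went from 5.4 ± 1.77 to 468.3 ± 82.8 (SD, n = 3 each; log2 difference 6.48, SE 0.417, adjusted p = 9.4e-05). AT4G30170, a class III peroxidase, went from 5.5 ± 2.15 to 320.9 ± 11.9 (log2 difference 5.94, SE 0.442, adjusted p = 0.000149). AT3G13610, the 2-oxoglutarate-dependent dioxygenase of scopoletin synthesis, rose by 5.06 (SE 0.436, adjusted p = 0.000387). OSM34, an osmotin-like protein, rose by 6.36 (SE 0.654, adjusted p = 0.000995), from 13.97 ± 13 to 819 ± 96.3. The acyltransferase-like AT4G15390 rose by 5.84 and the GDSL lipase AT5G45670 by 5.35. The TRAF-like genes AT5G26280 and AT5G26260, close to one another by locus code, rose by 7.54 (SE 0.459) and 5.50 (SE 0.592). AT2G10940 went from 38.57 ± 15.9 to 3250 ± 521 (log2 difference 6.48, SE 0.308, adjusted p = 2.06e-05). AT1G19530, AT5G22555 and AT5G62280 rose by 5.78, 5.74 and 5.40. All 14 had adjusted p-values of 0.00131 or less in the limma fit and kept their call without any single array. In 12 of them the wild type mean signal was at most 13.97, and the log2(signal + 64) differences of these 12 were smaller, from 1.33 for AT5G26260 to 3.51 for OSM34. On that scale AT5G26260, GH3.3 (1.72), AT5G45670 (1.77), AT5G22555 (1.83), AT1G19530 (2.18) and AT3G13610 (2.30) lay below the expansin gene EXPA8 (2.32), which is not among the 14.

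The falls were smaller and closer to the threshold. WSD1, a wax ester synthase of the cuticle, fell from 40.33 ± 10.9 to 4.93 ± 3.07 (SD, n = 3 each; log2 difference -3.21, SE 0.654, adjusted p = 0.0388). UGT76E12, a glycosyltransferase, differed by -2.98 (SE 0.589, adjusted p = 0.0342), AT4G07850 by -3.16 (adjusted p = 0.0298) and the MATE transporter AT1G23300 by -2.56 (adjusted p = 0.0401). In the arrays labelled tac1-1D these 4 had mean signals of at most 10.93, and their log2(signal + 64) differences were -0.59 for WSD1, -0.62 for UGT76E12, -0.72 for AT1G23300 and -0.50 for AT4G07850, which lost its call on that scale (adjusted p = 0.0681). AT3G24460 (adjusted p = 0.0824) and AT1G33260 (0.072) lost theirs too. At higher signals, the pectin acetylesterase AT1G57590 went from 2325 ± 1080 to 689.7 ± 178 (log2 difference -1.69, SE 0.301, adjusted p = 0.0214). TINY2, an AP2/ERF transcription factor, went from 227.6 ± 72.9 to 71.9 ± 3.3 (log2 difference -1.61, adjusted p = 0.0296). AT4G30650, of the low-temperature and salt responsive RCI2 type, went from 1231 ± 116 to 501.4 ± 34.5 (log2 difference -1.29, SE 0.141, adjusted p = 0.00142). The other 7 were AT1G60230 at -2.22, AT2G21820 at -1.63, AT3G24460 at -1.52, AT2G46940 at -1.36, AT4G35320 at -1.35, AT1G33260 at -1.34 and AT5G47060 at -1.31. Of the 14, 12 lost their call without tac1-1D replicate 2 and 12 without tac1-1D replicate 3. 11 did so without wild type replicate 2, 9 without wild type replicate 1, and 6 each without wild type replicate 3 and tac1-1D replicate 1. No sign changed.

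**Figure D2:**
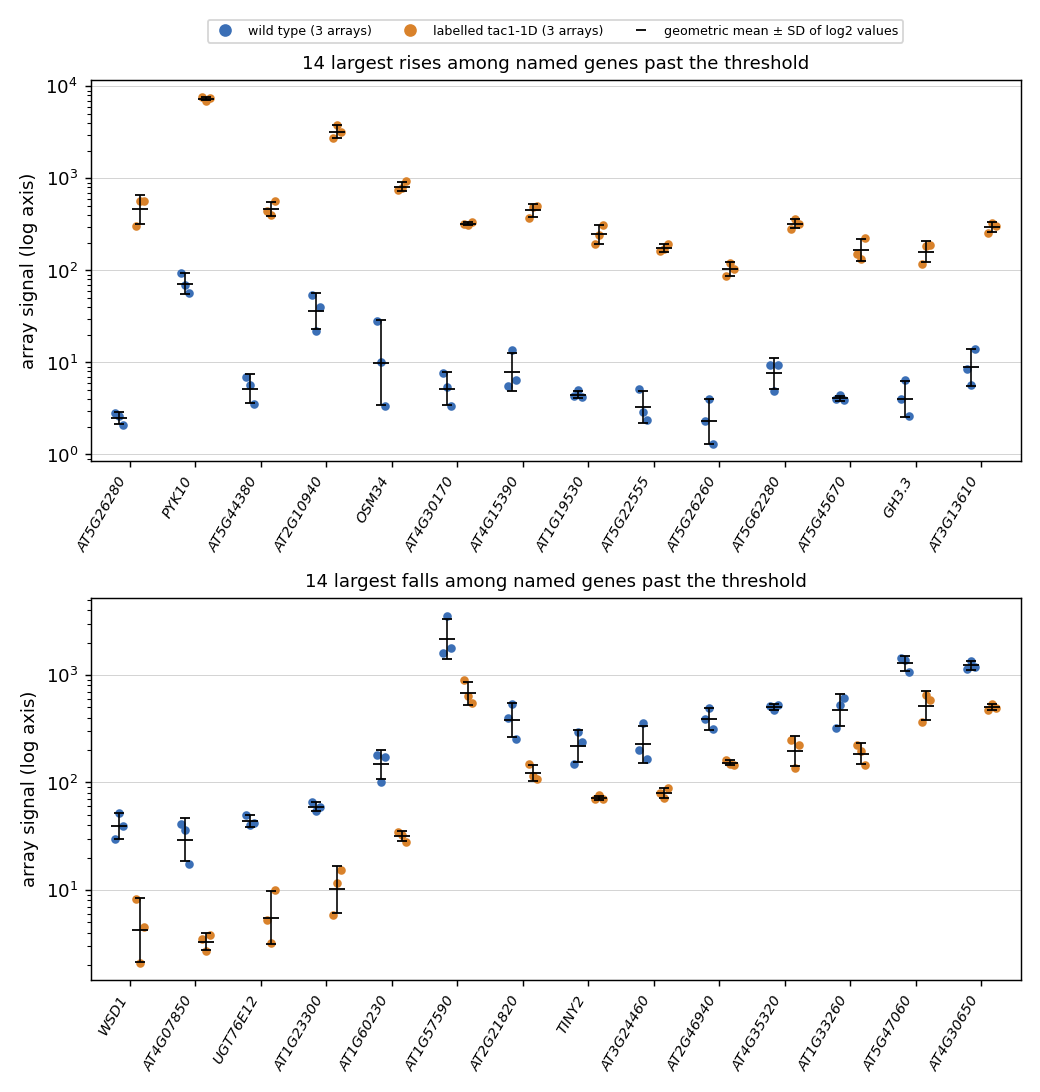
Array signal (log axis) of the 14 largest rises and the 14 largest falls among named genes past the threshold, with 3 arrays per genotype as points and the geometric mean ± SD of the log2 values as bars. All 3 arrays labelled tac1-1D lie on one side of the wild type arrays for each gene, and most of the large rises start from wild type signals under 20.

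Of the auxin response list, 10 members were measured, and 2 passed the threshold over all probe sets, both higher. They encode auxin-conjugating enzymes: GH3.3 rose by 5.30 (SE 0.525, adjusted p = 0.000824; 163.3 ± 40 against 4.33 ± 1.92, n = 3 each) and WES1 by 1.31 (SE 0.195, adjusted p = 0.00908; 410.5 ± 12.8 against 166.8 ± 28.6). WES1 lost its call without tac1-1D replicate 2 (adjusted p = 0.0624) or replicate 3 (adjusted p = 0.0629). Adjusted over the list alone 3 were higher, the other being GH3.17, a further GH3 gene, at 2.83. Its wild type mean signal was 20.93, and on the log2(signal + 64) scale it differed by 1. The transcription factor genes IAA20, IAA29, IAA30, LBD16, LBD29 and HAT2 and the gene GH3.1 did not pass, at -0.59 to 0.90. The list was shifted upward by camera (adjusted p = 0.00603), but not with an estimated correlation (adjusted p = 0.249). Beside this list, the root marker PYK10 rose by 6.68, and EXPA7 stood at 1.2 without passing.

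Of the cell wall loosening list, 4 members were measured and EXPA8, an expansin, rose by 3.83 (SE 0.508, adjusted p = 0.00456; 428.7 ± 101 against 35.67 ± 26.6, n = 3 each). Adjusted over the list alone 2 were higher, with the xyloglucan endotransglucosylase XTH16 at 2.25. XTH33 differed by 1.1 and EXPA4 by -0.42 without passing. The camera adjusted p was 0.0139 upward, and 0.249 with an estimated correlation. Beside these genes, the root marker PYK10 rose by 6.68, and EXPA7 stood at 1.2 without passing (adjusted p = 0.214).

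In the photosynthesis list, 1 of 5 measured members passed. LHCB4.2, a light-harvesting protein of photosystem II, rose by 1.04 (SE 0.201, adjusted p = 0.032; 6802 ± 725 against 3372 ± 849, n = 3 each), also adjusted over the list alone. LHCB4.1, PSAE-1, PSBW and RCA lay between -0.16 and 0.33. The adjusted p of the list was 0.0452 upward, and 0.252 with an estimated correlation. LHCB4.2 lost its call without tac1-1D replicate 2 (adjusted p = 0.157) or 3 (0.125) and without wild type replicate 2 (0.109) or 3 (0.0749), and the list had an adjusted p between 0.0539 and 0.119 without any of these 4.

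The abscisic acid, cold and drought list had 4 measured members, and none passed over all probe sets. Adjusted over the list alone 3 were lower. The chloroplast-protecting cold proteins COR15A and COR15B differed by -1.89 (SE 0.580; 2296 ± 1790 against 6558 ± 1450, n = 3 each) and -1.02 (SE 0.251; 1346 ± 475 against 2643 ± 496), with adjusted p-values of 0.155 and 0.0793 over all probe sets. The dehydrin LTI30 differed by -0.75 (adjusted p = 0.11), and COR47 by -0.03. The list had a camera adjusted p of 0.00603 downward, and 0.252 with an estimated correlation. For the flavonoid and anthocyanin list, DFR, UF3GT and AT5MAT had differences of -1.15, -1.21 and -1.11, none past the threshold, and a list adjusted p of 0.054 (0.367 with an estimated correlation). The arrays labelled tac1-1D stood far apart for these genes, with signals of 5743 ± 5150 for DFR against 9133 ± 3190 in wild type (SD, n = 3 each). The list adjusted p was 0.00413 without tac1-1D replicate 1, 0.0306 without wild type replicate 1 and 0.0377 without tac1-1D replicate 2, but 0.515 without tac1-1D replicate 3, 0.119 without wild type replicate 2 and 0.216 without wild type replicate 3. The guard cell and stomatal lineage markers SPCH, MUTE and FMA differed by 1.52, -0.68 and -0.16, with a list camera adjusted p of 0.985 (0.987 with an estimated correlation). SPCH and MUTE had low mean signals, 21.73 and 12.83 in the arrays labelled tac1-1D against 9.8 and 17.37 in wild type. On the log2(signal + 64) scale the 3 differences were 0.211, -0.087 and -0.126. On the log2 scale of the file the median of these markers was -0.157, while their mean was 0.228 and the test pointed upward.

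**Figure D3:**
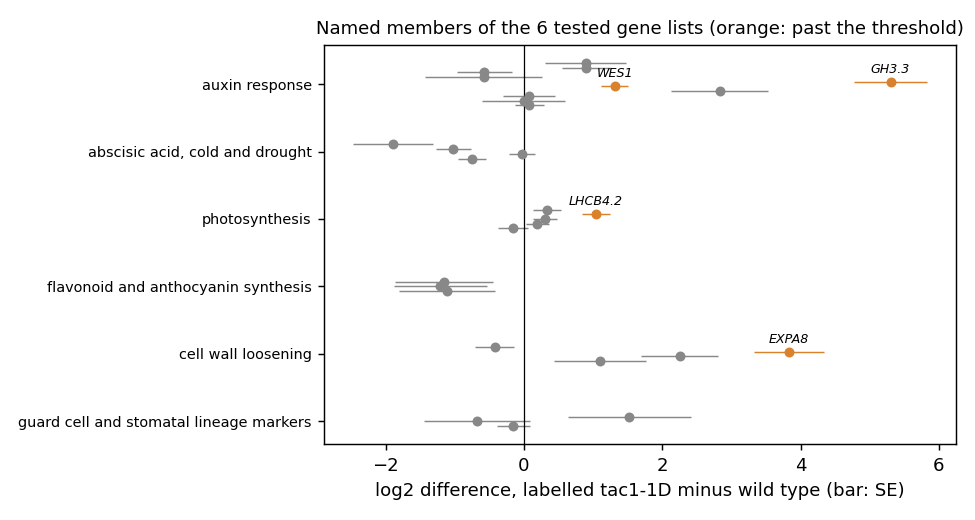
Log2 difference, arrays labelled tac1-1D minus wild type (3 each), of the measured members of the 6 tested lists, with the SE as bars. The members past the threshold, in orange, are GH3.3, WES1, LHCB4.2 and EXPA8, and all lie above 0.

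In the lists too small for a set test, AKINBETA1 and PYK10 passed over all probe sets. With 1 or 2 measured members, adjustment over the list alone corrects for at most 2 genes and not for the number of lists. A member higher or lower only by that adjustment is therefore weak evidence. AKINBETA1, a regulatory subunit of the SnRK1 kinase and the 1 measured gene of the sugar starvation list, rose by 1.53 (SE 0.197, adjusted p = 0.00391; 728.8 ± 131 against 251.5 ± 44.4, n = 3 each), also adjusted over the list alone. Of the root markers, EXPA7, a root hair expansin, differed by 1.2 (SE 0.424, adjusted p = 0.214), and both it and PYK10 were higher adjusted over the list alone. Of the telomere and telomerase proteins, TERT, the catalytic subunit of telomerase, differed by 0.66 (SE 0.453, adjusted p = 0.559; 45.7 ± 5.91 against 30.2 ± 11.9, n = 3 each) and STN1 by -0.21. Neither passed adjusted over the list alone. Of the salicylic acid list, SAG101 (0.94) and WRKY53 (1.89) were both higher adjusted over the list alone, and not over all probe sets. For WRKY53 the groups overlapped, with 241.7 to 1148.7 in wild type and 925.2 to 4627.5 in the arrays labelled tac1-1D. Its limma adjusted p over all probe sets was 0.191. Of the jasmonate list, THI2.1 (-2.03) was lower adjusted over the list alone but not over all probe sets (limma adjusted p = 0.195). PDF1.2 stood at 0.98. No measured member of the circadian clock, cell cycle, cytokinin, glucosinolate, heat shock, touch response, leaf senescence and shoot meristem lists passed over all probe sets or adjusted over the list alone. They were GI, PRL, ARR15, RR16, UGT74B1, BCAT4, ATHSP22.0, STZ, CML38, SAG29, WRKY6 and CLV3, and their differences ran from -1.81 for SAG29 to 0.59 for STZ.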

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

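The pseudocount of 16 had been planned for the main fit and became an alternative after the data were seen. The share of rises among calls with neither group at low signal was also chosen after that. So were the threshold of 2-fold on the log2 scale of the file and the minimum list size. The other alternatives were planned. TAC1 was lower and past no threshold under every alternative that kept it; the 40th percentile filter removed it. PYK10 was the 1 called neighbour under every alternative. None of the 561 calls changed sign in any refit. Their groups did not overlap, so only quantile normalization and median centring could have changed a sign, also for the named genes. The share of the 561 that kept their call ranged from 99.3% with a pseudocount of 1 to 15.5% with the plain t-test. It was 43.7% without the intensity trend, and 37.6% and 38% without tac1-1D replicates 2 and 3. Without wild type replicate 3, 582 probe sets passed, and 431 of them were among the 561. None of the 32 other named genes changed sign where a setting kept it, and the lost calls were mostly falls: 9 falls and 1 rise without the intensity trend, 13 falls and 7 rises with the plain t-test. With the pseudocounts of 16 and 64, 2 and 3 falls were lost. Among the limits of the results are the number of arrays, the unnamed probe sets and, for low signals, the missing background reading.

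Without the intensity trend 265 probe sets passed, 245 higher and 20 lower. The plain t-test on the log2 values gave 96 (88 higher, 8 lower; 2868 at an unadjusted p under 0.05). At an adjusted p under 0.10 there were 988, 731 higher and 257 lower, which made 73.99% rises. Falls numbered 132 with the 40th percentile filter, 140 with median centring, 47 at 2-fold and 41 at 2-fold on the log2(signal + 16) scale. Without 1 array, the calls ranged from 212 to 582, the rises from 201 to 498, the falls from 11 to 145 and the share of rises from 73.15% to 94.81%. The lowest counts came without tac1-1D replicate 2 and the most falls without tac1-1D replicate 1. Beyond fewer arrays, fewer probe sets or another threshold, the cause was not tested.

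The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.0542, -0.0104 and -0.0544, and no array correlated best with its own number. With the replicate block 422 probe sets passed, 48 of them lower, the adjusted p of the photosynthesis list was 0.05817 and that of the flavonoid list 0.04394.

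4 lists passed with the preset correlation, 0 with camera on an estimated correlation (0 at an unadjusted p under 0.05), 0 with camera on ranks (4 at an unadjusted p under 0.05) and 2 with fry, which tests a list by itself. With the estimated correlation the adjusted p was 0.2488 for auxin response and cell wall loosening and 0.2517 for the abscisic acid list and photosynthesis. On ranks it was 0.06687 for auxin response and photosynthesis, 0.06534 for the abscisic acid list and 0.1094 for cell wall loosening. With fry it was 0.1459 for the abscisic acid list and 0.05912 for photosynthesis. Photosynthesis also missed the threshold with a pseudocount of 1 (0.05021), median centring (0.0679) and no intensity trend (0.05438), and ranged from 0.02114 to 0.119 without 1 array. Flavonoid synthesis ranged from 0.004125 to 0.515 without 1 array. The guard cell list, never called, turned direction without wild type replicate 2 (0.5899) or tac1-1D replicate 2 (0.605), and with pseudocounts of 16 (0.9898) and 64 (0.975), quantile normalization (0.9286), no intensity trend (0.9802), the replicate block (0.9989), ranks (0.9495) and fry (0.8802), and ranged from 0.5899 to 0.889 without 1 array. The cause was not tested. The robust variance model does not apply to camera and gave no list values.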

Other observations

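The lists of root hair, other root and ER body genes, the grouping by chromosome, the symbol families, and the tests of TAC1's probe set, of PYK10 alone, of low signals and of other splits were chosen after results had been seen. Of 12 further root genes with a named probe set, 3 peroxidase genes rose in the arrays labelled tac1-1D: AT1G30870 by 2.43, AT2G18980 by 2.76 and AT5G66390 by 3.6 (limma adjusted p = 0.0167, 0.0272 and 0.0062). Their signals stayed low, at 113.9 ± 13.7, 136.5 ± 6.22 and 60.67 ± 9.36 (SD, n = 3), and their log2(signal + 64) differences were 1.05, 1.21 and 0.85. Of 12 root hair genes, the peroxidase AT4G26010 rose by 2.96 (adjusted p = 0.0062), or 1.3 on the log2(signal + 64) scale. The median of the other root genes was 1.11 (camera adjusted p = 1.64e-06 over the 3 added lists, raw p = 5.46e-07; with an estimated correlation adjusted p = 0.0692, raw p = 0.0289) and that of the root hair genes 0.72 (camera adjusted p = 7.59e-05, raw p = 5.06e-05; with an estimated correlation adjusted p = 0.0692, raw p = 0.0461). Of 3 ER body genes, NAI2, which encodes an ER body component, rose by 3.28 (2.53 on the log2(signal + 64) scale; SE 0.337, adjusted p = 0.000999; 798.9 ± 35.2 against 90.67 ± 50.5), while NAI1, the regulator of ER body formation, stood at 1.39 and JAL23 at -1.07 without passing (camera adjusted p = 0.0595; adjusted p = 0.215 with an estimated correlation).

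Among 69 genes of the plastid genome, 4 rose in the arrays labelled tac1-1D and none fell past the threshold, and 58 had a difference above 0. The rises were ycf4 by 1.42, cemA by 1.36, rpl14 by 1.14 and rps2 by 1.1 (limma adjusted p = 0.0148, 0.00428, 0.0175 and 0.031). ycf4, cemA and petA lie in one transcription unit, and petA stood at 0.89 (adjusted p = 0.13). The plastid median was 0.327, 0.345 with quantile normalization and 0.248 with median centring, and 0.161 to 0.436 without any 1 array. The plastid genes were shifted against all others by camera (adjusted p = 6.87e-09), but not with an estimated correlation (adjusted p = 0.69). Of 46 symbol families of at least 5 genes, 4 passed upward with the preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05). They were the plastid ribosomal rpl and rps genes, the XTH genes, with XTH18 at 4.11 (adjusted p = 0.0135), or 1.33 on the log2(signal + 64) scale, and the PDF symbols. The last mix defensins, of which PDF2.1 rose by 3.27 (adjusted p = 0.0321), or 0.732 on the log2(signal + 64) scale, with the peptide deformylases PDF1A and PDF1B, at 0.28 and -0.21. Their camera adjusted p-values were 0.000248, 0.0394, 0.0303 and 0.0275, and 0.504, 0.708, 0.675 and 0.708 with an estimated correlation.

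PYK10, 3 of the 12 other root genes and 1 of the 12 root hair genes rose in the arrays labelled tac1-1D, while neither added list passed with an estimated correlation. Root tissue in the leaf samples would bring root hair and other root transcripts alike. The root hair genes had a median of 0.72 with a 95% bootstrap range of 0.196 to 1.35, and the other root genes 1.11 with 0.397 to 2.81. The median wild type signals of these 2 lists were only 46.6 and 43.5, so these folds are uncertain. Root tissue may or may not account for the pattern and cannot be told apart from a change in the leaves. Within 20 genes of TAC1 lay 1 of 211 called rises of named genes, 0.474% (exact upper 95% limit 2.61%). Only 21 genes with a named probe set lie there, so a small share was fixed in advance and is no test. Direct action of tag enhancers on these neighbours leaves the other called rises of named genes unexplained. Indirect effects through a neighbour were not tested. For PYK10 alone, enhancers that reach it and leave the other neighbours (median -0.144) are neither shown nor excluded by these values, and any other effect of genotype stays open too.

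Many more probe sets rose than fell past the threshold. If the scaling of the arrays were the whole cause, another scaling should bring the share of rises under 60%. The arrays labelled tac1-1D did have higher median signals, 185.7 to 195.1 against 178.6 to 181.7. Yet the median log2 difference over all probe sets was -0.012 as deposited. Quantile normalization moved it to -0.0573 and median centring to -0.0914. The share of rises was 84.57% with quantile normalization and 75.48% with median centring (exact 95% range 71.7% to 79.0%, treating probe sets as independent). The bound of 75% set beforehand was thus met only narrowly. Among the 306 calls whose lower group had a mean signal at or above the 40th percentile (113.6), 231 were rises, or 75.5% (70.3% to 80.2%), which argues against low signals as the whole cause. The 255 calls left out were 245 rises and 10 falls, so a part of the excess may come from probe sets that start at low signals. This split does not measure that part, since a larger change by itself lowers the signal of the lower group. For scaling the settings differ: falls numbered 85 as deposited, 140 with median centring and 79 with quantile normalization. A difference in leaf composition or genotype was not tested.

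TAC1's probe set was not higher in the arrays labelled tac1-1D. Exchanged genotype labels are neither shown nor excluded. TAC1 was lower in the arrays labelled tac1-1D without passing the threshold (limma adjusted p = 0.47), at signals of at most 9.5 on any array. A probe set that does not report the transcript at these levels is another candidate explanation. Both were to be tested by the rank of TAC1 on its array. Exchanged labels were to put it above the 40th percentile in the arrays labelled wild type, with a difference past the threshold. It met neither condition. At most 11% of probe sets lay below it in the arrays labelled wild type and at most 5.8% in those labelled tac1-1D. A probe set that does not report the transcript would miss these conditions too. That rank also sets different probe sets against each other, so it decides neither explanation, and no second probe set names TAC1. These explanations cannot be told apart from a TAC1 transcript that is too scarce in leaves of this age.

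The 6 arrays can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 561 probe sets and the highest other split 0 with limma (3446 and 1551 at an unadjusted p under 0.05), so that 1 of the 10 reached the real count, the real split itself. None of the 64 array control probe sets differed between the genotypes after adjustment with limma, and 0 had an unadjusted p under 0.05. The 3' to 5' signal ratios are lower in more intact RNA. For GAPDH they were 1.06 to 1.42 in wild type and 0.883 to 1.17 in tac1-1D. For 1 pair of actin controls they were 6.76 to 7.75 in wild type and 5.64 to 10.9 in tac1-1D. Another actin pair had mean 3' and 5' signals of 8364 and 3514 in wild type, and 6863 and 2883 in tac1-1D.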
